A study of Homo sapiens with 2 samples.

How the data were processed

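The series holds 2 chromatin libraries from U87MG, a human glioblastoma cell line, both from cells given LY294002, an inhibitor of phosphoinositide 3-kinase. One is a FLAG immunoprecipitation and the other is input chromatin. Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 min, the fixation was quenched for 5 min and the chromatin was sonicated for 10 min. Per the submitters' processing notes, the genome build was hg19 and the tools were Trimmomatic, HISAT2 and MACS2, with no version, role or parameter. The read filters, the treatment of duplicate and multiply mapped reads, the peak threshold and the library used as control are not given in the sources used here. Replicates of the immunoprecipitation were not analysed here, so every value describes 1 library and no difference between conditions was tested.

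One peak list was analysed, that of the FLAG library. Its layout is the narrowPeak format of MACS2, with a start, an end and a summit per peak. The deposited fold enrichment is a ratio of the ChIP pileup at the summit to the background estimated by the caller. The deposited significance columns are the −log10 p-value and the −log10 q-value of the summit, as the authors' caller gave them. The deposited score column equals the whole part of 10 times the −log10 q in 100% of rows. The smallest −log10 q was 1.31, which is a q of 0.049. All of these per-peak values are the authors'. They were used to describe, rank and filter peaks within this list and to recover the pileup and background of each peak, on which the intervals of fold and the tests of background rest. Starts are given here counting from 1.

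MACS2 computes the fold as pileup plus 1 over background plus 1, and p as the upper Poisson tail of the pileup given the background. Both were therefore solved together for each peak, for a whole-number ChIP pileup and a background. In all 9717 peaks the recovered pair gave back the deposited −log10 p-value to within 0.001, with a largest error of 5.0e-04. Tested on simulated data, the same step returned the true pileup, and the true background within 0.01 tags, in 2000 of 2000 simulated peaks. The simulated peaks did not reach the largest pileups or the lowest folds of the list. The finer tolerance used below for whole multiples was not tested in this way. The lowest recovered background was 3.65 tags per position, a value shared by 1859 peaks and taken as the genome-wide background of the caller. Of the 7815 higher backgrounds under 20 tags, 53.7% were whole multiples of 0.931 tags within a tolerance of 2e-04. All of the rest (100%) were whole multiples of the step that a 10 kb window gives with tags extended to 150 bp. These values imply that a control library 1.07 times as deep as the ChIP library entered the peak calls. The genome-wide background corresponds to 24.3 ChIP tags per kb of effective genome, and the effective genome size set in the caller is not given in the sources used here. The recovered pileups give each fold a 95% Poisson interval (exact), which covers counting error only. It leaves out the error of the background and any difference between cultures, and sequenced tags are not independent molecules.

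At this depth the smallest called pileup was 13 tags, which against the genome-wide background is a fold of 3.01. A site of lower enrichment over that background could not enter the list.

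Peaks on chromosomes 1 to 22 and X entered the comparisons. Peaks per Mb were taken over the span from the first to the last summit of a chromosome, since no sequence or annotation of hg19 was used here. Differences in density between a chromosome and the other autosomes were tested by a two-sided permutation test of 5 Mb bins with 100000 permutations and Benjamini-Hochberg adjustment over 23 chromosomes. The median distance between neighbouring summits was compared with 1000 uniform placements between the first and last summit of each chromosome, in a two-sided permutation test. These placements do not avoid assembly gaps. Tested on simulated lists, the distance test gave p under 0.05 in 1 of 40 uniform lists and in 40 of 40 clustered lists. The simulated lists had no gaps, so they do not give the false-positive rate on a genome with gaps. Bins and peaks of 1 library are not replicates, so these p-values describe this list only. Neighbouring bins were treated as exchangeable, so a run of adjacent dense bins makes the p-value of a chromosome too small. The comparison of chromosomes, the runs of strong peaks and the dense segments were chosen after seeing the data. Dense segments were defined as runs of 1 Mb bins with at least 15 summits, joined where such bins lay at most 3 Mb apart, with at least 50 summits in all. For chromosome X, the autosomal peaks outside the dense segments were thinned to 0.5 of their tags, with the background lowered to the same share but not under the genome-wide value, and kept where they still reached the smallest −log10 p in the list, and the width that the caller requires was not applied. Ratios to the expected number have exact Poisson intervals of the X count. Ratios of peaks per Mb have exact conditional binomial intervals at the 95% level. Both kinds of interval treat peaks as independent and are too narrow where peaks lie in clusters.

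Of 10 results planned before the data were examined, the peak counts and the distance between summits were run, and 8 need the sequence or gene annotation of hg19 and were not run. They are the position of peaks relative to transcription start sites and gene parts, the forkhead and other motifs, 7-mers, motif share by strength, strength by position, and fixed gene lists. The gene table at hand belongs to GRCh38.p14, so no gene was assigned to a peak. The rule for named peaks, also fixed beforehand, was to name the 25 of highest fold on these chromosomes. Its exclusion of repeat-masked and centromeric peaks was not applied, for lack of the sequence, and its genes chosen by name were not analysed. Of the other settings chosen beforehand, those run were stricter thresholds (−log10 q of 5 or of 10, fold of 5) and merging of neighbouring peaks. Those added after seeing the data were the same thresholds for the comparison of chromosomes, leaving out dense segments or peaks of high background, and other definitions of a segment. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.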

Results

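The series addressed where FOXO3, a forkhead transcription factor that is kept out of the nucleus when phosphoinositide 3-kinase signalling is active, binds the genome of U87MG cells. In CETCh-seq, genome editing adds an epitope tag to the endogenous factor, here FLAG, and an antibody against the tag replaces one against the factor. Both libraries of the series came from cells treated with LY294002, an inhibitor of phosphoinositide 3-kinase. The labels give the genotype of both samples as wild type and do not say whether the input came from tagged cells. The deposited peak list of the FLAG library held 9717 peaks, each with its own summit, covering 2.76 Mb in all. Of these, 9670 lay on chromosomes 1 to 22 and X, and 47 lay on other sequences. The depth implied by the peak values was 24.3 ChIP tags and 26.1 control tags per kb of effective genome. With 1 ChIP library, intervals cover counting error only.

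Most FLAG peaks were narrow and of modest enrichment, and a small set stood far above the rest. The median fold enrichment was 3.88, with quartiles of 3.36 and 4.798 and a highest value of 40.3. Folds of 5 or more were seen in 2147 peaks (22.1%), folds of 10 or more in 220 peaks (2.26%) and folds of 20 or more in 7 peaks. The median width was 246 bp, with a range from 150 to 1473 bp. The 2451 peaks on chromosomes 1 to 22 and X with a −log10 q of 10 or more were wider, with a median of 386 bp against 218 bp for the 7219 others. Across these 9670 peaks, which are not independent replicates, width and fold had a Spearman correlation of 0.44. Width, fold and q of a peak all derive from the same pileup, so they are not independent measures.

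The pileups recovered from the deposited fold and p-value had a median of 25 tags at the summit, with quartiles of 19 and 36 tags. The background estimated by the caller had a median of 5.59 tags. It equalled the genome-wide background of 3.65 tags in 1859 peaks (19.1%), where no local window of the control exceeded that level. A further 18 peaks lay on backgrounds of at least 10 times this level, between 39.1 and 1137 tags, and their median fold was 2.18. Of these peaks, 7 lay on numbered chromosomes. They included 3 on chromosome 16 between 46391293 and 46404698, 3 on chromosome 2 between 92317683 and 92322805, and 1 on chromosome 8 from 43824666 to 43824975 (hg19), with folds from 1.22 to 2.26.

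**Figure D1:**
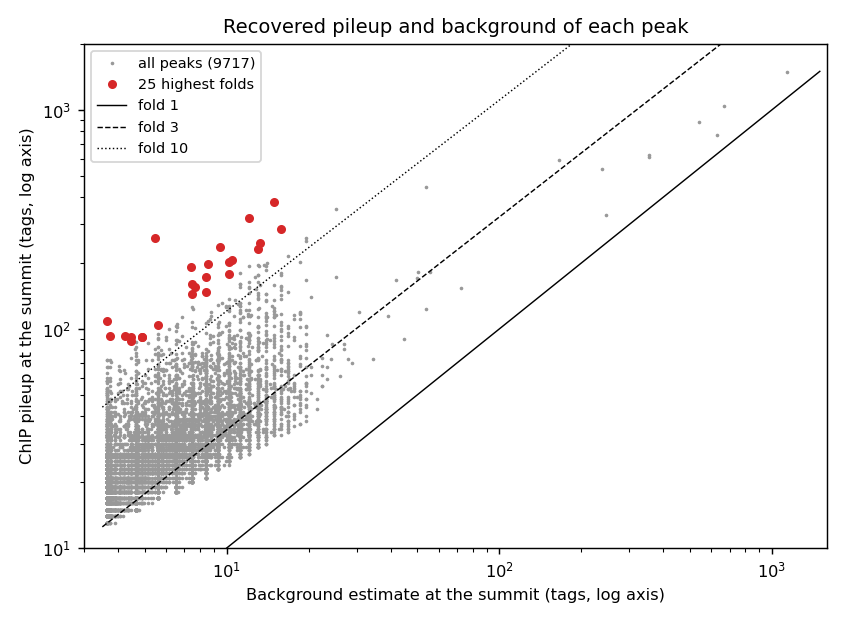
ChIP pileup at the summit (tags, log axis) against the caller's background at the same position (tags, log axis) for the 9717 peaks, as recovered from the deposited fold and p-value, with lines of equal fold. Grey points are all peaks and red points are the 25 of highest fold, whose pileups run from 88 to 380 tags on backgrounds between 3.65 and 15.8 tags.

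The peak of highest enrichment lay on chromosome 5 from 90675580 to 90676193 (hg19). Its fold was 40.3, with a 95% Poisson interval from 35.6 to 45.5, from 259 ChIP tags over a background of 5.45 tags. This interval did not overlap that of any other peak among the 25 of highest fold. The next was on chromosome 19 from 50380286 to 50381080, with a fold of 24.5 (21.9 to 27.3) from 320 tags over 12.1. A peak on chromosome 18 from 9475107 to 9475920 had the largest pileup of the 25, 380 tags over 14.9, and a fold of 24.0 (21.6 to 26.5). The chromosome 5 peak from 142735252 to 142735933 reached a fold of 23.6 (19.5 to 28.5) from 109 tags over the genome-wide background of 3.65 tags. On chromosome 16 the peak from 30107365 to 30107691 was only 327 bp wide and had a fold of 22.9 (19.8 to 26.4). Chromosome 7 held peaks from 27702403 to 27703155, with a fold of 22.6 (19.8 to 25.6), and from 106808761 to 106809484, with a fold of 20.9 (18.1 to 24.0). The intervals of these 6 peaks, ranked from the second to the seventh, overlapped one another, so their order was within counting error.

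The peaks ranked lower among the 25 had folds between 15.8 and 19.9. They included chromosome 3 from 17519989 to 17520640 (fold 19.9, interval 16.1 to 24.3), chromosome 12 from 12849337 to 12850018 (fold 19.1, interval 16.2 to 22.2) and chromosome 1 from 206847914 to 206848623 (fold 18.4, interval 15.8 to 21.4). On chromosome 15, 3 of the 25 were found. The peak from 74753248 to 74753879 had a fold of 18.1 (15.8 to 20.8). The others lay from 99191708 to 99192025 with a fold of 15.9 (13.1 to 19.3) and from 99395320 to 99396333 with a fold of 16.6 (14.5 to 18.9). Chromosome 22 held peaks from 31451484 to 31452071 (fold 18.1, interval 15.4 to 21.1) and from 41042180 to 41042786 (fold 17.3, interval 14.6 to 20.3). Across the 25, the peaks fell on 16 chromosomes, with no more than 3 on any of them and none on chromosome 13 or X. Their median width was 682 bp, and each had a −log10 q of at least 74.8. The genes at these positions were not analysed here.

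**Figure D2:**
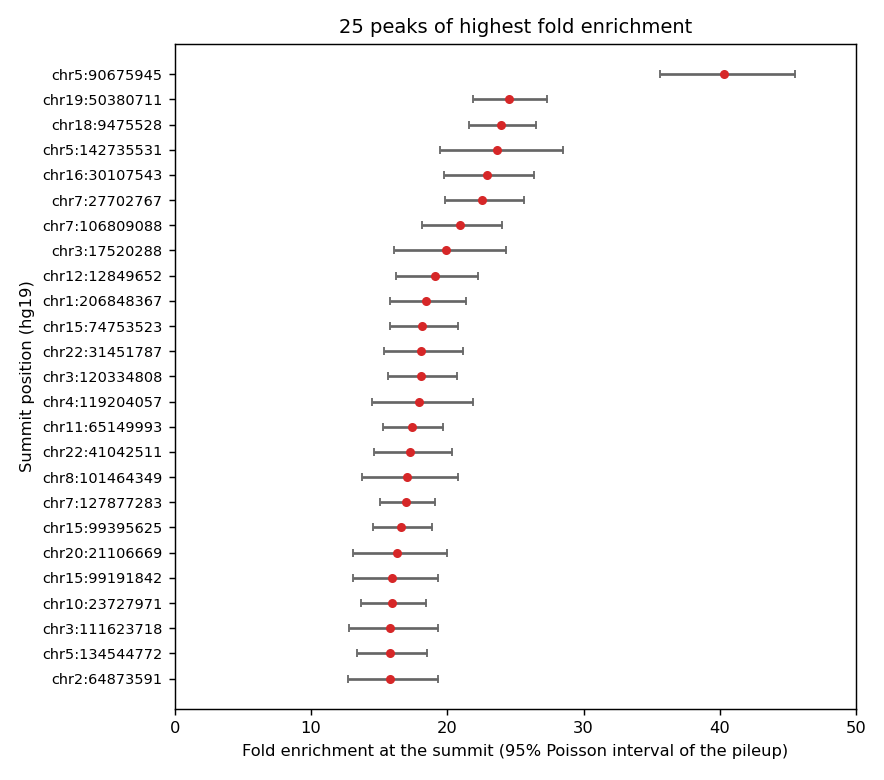
Fold enrichment at the summit of the 25 peaks of highest fold on chromosomes 1 to 22 and X, by hg19 summit position. Points are the deposited folds and bars the 95% Poisson intervals of the recovered pileup, which cover counting error only, and the interval of the top peak (35.6 to 45.5) lies clear of the others.

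Summits lay closer to one another than uniform placement gives. The median distance between neighbouring summits was 99.6 kb, against 183 kb in random placements (179 to 188 kb in the central 95% of them). This was a ratio of 0.54 with a permutation p of 0.001, the smallest that 1000 placements can give. The placements did not avoid assembly gaps, so this p does not separate clustering from the absence of peaks in gaps. The same holds for the random placements below. Within 1 kb of the next summit lay 221 of 9647 neighbouring pairs (2.29%), and within 10 kb lay 1338 pairs (13.9%). The peaks with a −log10 q of 10 or more were also closer than random, with a median of 536 kb against 769 kb (ratio 0.70, permutation p = 0.001). With a definition of runs chosen after the peaks were seen, 2 runs of at least 4 such peaks, each within 50 kb of the next, were found, against a mean of 0.25 and at most 3 in random placements (one-sided permutation p = 0.026). They lay on chromosome 1 between 185339163 and 185389069, with folds up to 8.83, and between 145098237 and 145196075, where 12 peaks of any strength were called and the highest fold of the 4 was 5.25.

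Peaks were unevenly spread over the chromosomes, with the highest density on chromosome 13 and the lowest on chromosome X. Chromosome 13 held 1080 peaks over 93.5 Mb, or 11.6 per Mb. In 5 Mb bins its density was 11.9 ± 13.1 peaks per Mb (SD, 18 bins), against 3.21 in 520 bins of the other autosomes. This was a ratio of 3.72, with a permutation p of 1e-05, the smallest that 100000 permutations can give, and an adjusted p of 2.3e-04. The excess lay in runs of adjacent bins, which the permutation treats as exchangeable, so this p overstates the evidence. Without the bins of dense segments the ratio was 1.21 over 11 bins (adjusted permutation p = 0.425). Chromosome X held 82 peaks over 153 Mb, with 0.52 ± 0.48 per Mb (SD, 30 bins) against 3.505 in 538 autosomal bins. Its ratio was 0.15 (permutation p = 8.9e-04, adjusted p = 0.0102). The comparison of chromosomes was not planned and was chosen after the peaks were seen. Chromosome 7 had 5.26 ± 4.82 peaks per Mb (SD, 31 bins), a ratio of 1.55 that did not pass adjustment (permutation p = 0.016, adjusted p = 0.123). With peaks of a −log10 q of 5 or more its ratio was 1.35 and passed (adjusted permutation p = 0.0416). None of the other chromosomes passed, and their ratios ran from 0.58 on chromosomes 11 and 16 to 1.18 on chromosome 10.

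The 2 chromosomes parted when only peaks with a −log10 q of 10 or more were counted. Chromosome X stayed low, with 14 such peaks and 0.093 ± 0.136 per Mb (SD, 30 bins) against 0.886 on the autosomes (ratio 0.11, adjusted permutation p = 2.3e-04). Chromosome 13 had 93 such peaks and 1.00 ± 0.62 per Mb (SD, 18 bins) against 0.882 in the other autosomes, a ratio of 1.13 that was within the spread between bins (adjusted permutation p = 0.876). The weaker peaks of chromosome 13, in contrast, had a ratio of 4.70 (adjusted permutation p = 2.3e-04). Among peaks with a −log10 q of 10 or more the next lowest chromosome was 18, with 34 peaks and a ratio of 0.51, which did not pass adjustment (permutation p = 0.0114, adjusted p = 0.131).

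**Figure D3:**
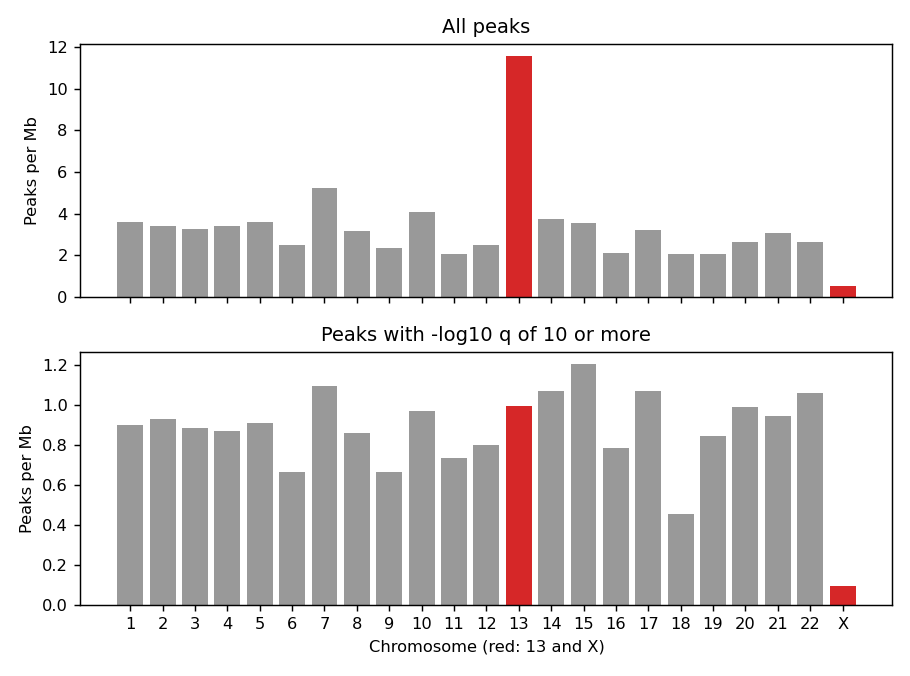
Peaks per Mb between the first and last summit of each chromosome, for all peaks (top) and for peaks with a −log10 q of 10 or more (bottom), each bar being 1 chromosome. Chromosomes 13 and X are red, and chromosome 13 stands out at 11.6 peaks per Mb among all peaks but not among the strong ones, while X is lowest in both.

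The excess on chromosome 13 lay beyond position 62615263 and had counterparts on 4 other chromosomes. From 53029215 to 62615263 no summit was called, a gap of 9.59 Mb. Beyond it, the segment from 63075690 to 72874662 held 360 peaks (36.7 per Mb) and the segment from 76064285 to 94982206 held 480 peaks (25.4 per Mb). Chromosome 10 had 124 peaks between 52072908 and 54624220, which is 48.6 per Mb and the highest density of these segments. Chromosome 7 had 155 peaks between 122030116 and 126999210 and 59 peaks between 135074614 and 137809874. Shorter segments with 66 and 60 peaks lay on chromosome 1 between 105146128 and 106990628 and on chromosome 5 between 69006015 and 70897726. These 7 segments made up 1.55% of the autosomal span and held 13.5% of the peaks on chromosomes 1 to 22 and X, whereas the remaining autosomal span had 3.05 peaks per Mb.

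Peaks in the dense segments were weaker than elsewhere. Their median fold was 3.65 and their median pileup 17 tags, against 3.98 and 27 tags in the remaining autosomal span. Peaks with a −log10 q under 10 were 13.3 times as frequent per Mb inside the segments (95% interval 12.5 to 14.2). Those with a −log10 q of 10 or more were 1.69 times as frequent (1.29 to 2.16). By segment, the strong peaks had a ratio of 1.05 (0.48 to 1.996) in the first of chromosome 13 and of 1.63 (1.07 to 2.38) in the second. On chromosome 10 the ratio was 3.58 (1.55 to 7.07), from 8 strong peaks. On chromosome 7 it was 0.92 (0.25 to 2.36) in the first segment and 3.76 (1.72 to 7.15) in the second. The segments were chosen for their number of peaks of any strength, so none of these ratios is independent evidence of an excess. The intervals treat peaks as independent and are too narrow where peaks lie in clusters.

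**Figure D4:**
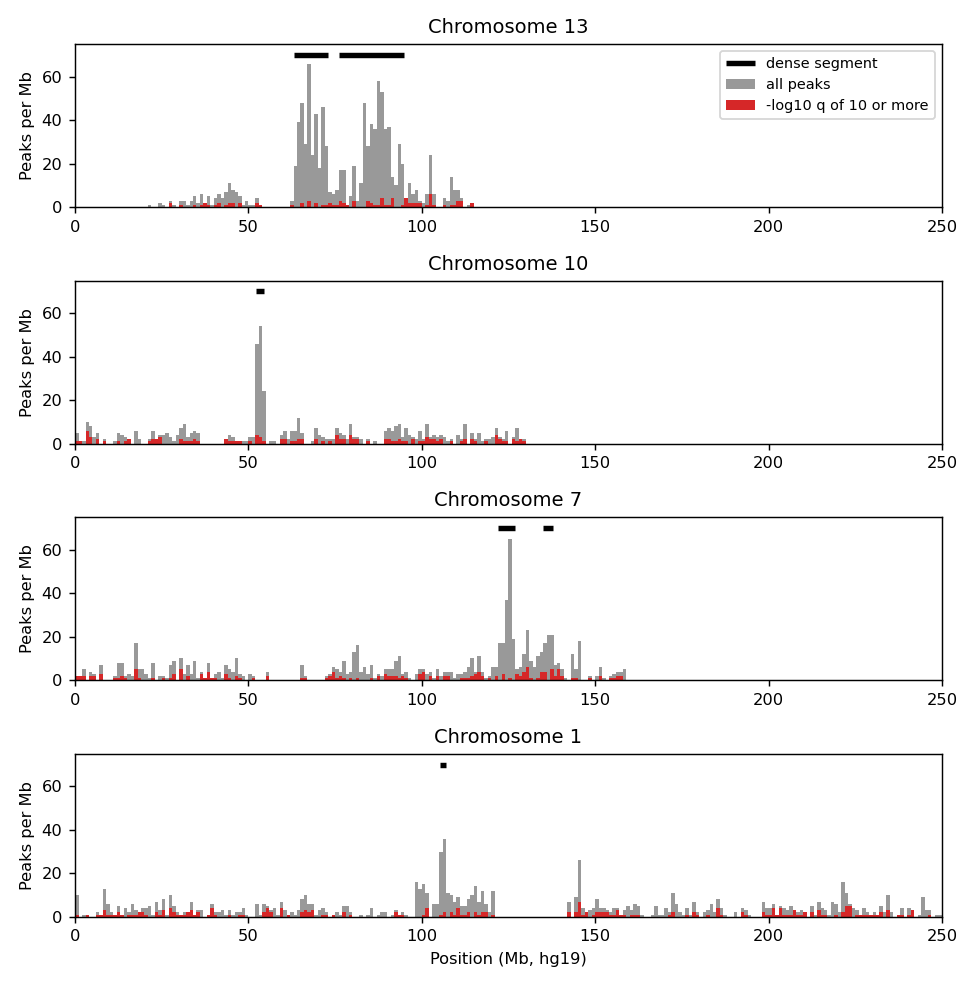
Peaks per Mb in 1 Mb bins along chromosomes 13, 10, 7 and 1 (position in Mb, hg19). Grey bars are all peaks, red bars those with a −log10 q of 10 or more and black lines the dense segments, where the grey bars rise (48.6 peaks per Mb on chromosome 10) by more than the red bars.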

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

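The tests of strong against weak peaks, of control coverage and of chromosome X, and the way segments were grouped in them, were chosen only after the result was seen, and the test of the pileup tail was set before. Outside the chromosomes compared in the report, 42 peaks lay on 13 alternate, unplaced or unlocalized sequences of hg19, a signal in data that no comparison used. The highest fold among them was 11.995, from 78 tags over a background of 5.59, on an alternate haplotype of chromosome 17. Some of the others lay on very high backgrounds, such as a peak with 445 tags over 54.0 on an unlocalized sequence of chromosome 7.

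The excess of weak peaks in the 7 dense segments was weighed against 3 explanations. The intervals used for this treat peaks as independent and are too narrow where peaks lie in clusters. Clusters of sites of ordinary strength would raise strong and weak peaks alike, if local depth is that of the remaining span. Under that condition, this is argued against as the whole cause in 6 segments taken singly. They lie on chromosomes 1, 5, 7 (first), 10 and 13 (both). Strong peaks there were 1.86, 1.81, 0.92, 3.58, 1.05 and 1.63 times as frequent as outside. These ratios rest on only 3, 3, 4, 8, 9 and 27 strong peaks, with intervals of 0.38 to 5.44 on chromosome 1 and 0.37 to 5.30 on chromosome 5. Weak peaks were 15.7, 13.8, 13.9, 20.9, 16.4 and 11.0 times as frequent, with separate intervals in each. The explanation stays open in the second segment of chromosome 7, with 3.76 (1.72 to 7.15) and 8.39 (6.22 to 11.1). Strength was split by q, which falls with local depth, and local depth was not measured. Low control coverage would place more of the peaks with at most 20 tags at the genome-wide background than expected at the same pileups. On chromosomes 1, 5 and 13 this was seen, with 58.6% (55.1 to 62.1) against 45.1%, and low control coverage stays open there. In the first segment of chromosome 7 it stays open too, but undecided, with 36.1% (27.6 to 45.3) against 42.8%. It is argued against on chromosome 10, with 22.7% (13.8 to 33.8) against 42.0%. In the second segment of chromosome 7 the share was 21.4% of 28 peaks (8.30 to 40.95) against 40.96%. By the rule of this test, an upper bound under the expected share argues against low control coverage. Here the bound lies under it so narrowly that the explanation is left open. The expected share there is itself estimated from peaks outside the segments, whose own share had an interval of 37.8 to 42.1. A raised ChIP background relative to the control stays open, since its test, the percent of peaks at the genome-wide background with 22 tags or more (3.84% inside, 28.5% outside), restates the excess of weak peaks and decides nothing, and no biological explanation was tested, since the design gives no group for one.

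The low number of peaks on chromosome X was weighed against X being present at 0.5 times the copies of an autosome. A first test, which wrongly leaves the local background as it was and so decides nothing, found that X peaks of fold 3, 4, 5 and 6 or more were 1.18 (0.93 to 1.48), 2.06 (1.54 to 2.73), 1.81 (1.11 to 2.81) and 1.38 (0.58 to 2.82) times as frequent per Mb as autosomal peaks of fold 6, 8, 10 and 12 or more outside the dense segments. With the background lowered too, the 8284 autosomal peaks outside the dense segments were thinned to 0.5 of their tags, which left 252 peaks expected on X against 82 called, a ratio of 0.33 (0.26 to 0.40), and 44.8 strong peaks against 14, a ratio of 0.31 (0.17 to 0.52). Of the X peaks 32.9% sat at the genome-wide background (22.9 to 44.2), which lies between the 15.2% of these autosomal peaks outside the dense segments as called (1256 of 8284) and the 50.5% after thinning. Fewer peaks were called on X than the thinned values give. These values were simulated from autosomal peaks, at a share of 0.5 only and without the width that the caller requires. The background was lowered by a fixed share and the control counts were not redrawn. The 50.5% therefore leaves out the counting error of the control. Copy number was not measured. A lower copy number and a lower density of sites on X therefore cannot be told apart, and no biological explanation was tested.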

How the results depend on the processing

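The tests on chromosomes X and 13 and on dense segments, and the settings without dense segments or high backgrounds, were chosen only after the result was seen. Of 28 alternative settings over 6 results, 22 kept the direction and the side of the threshold or, for the number of peaks, stayed within 1.5 times, and none reversed. Several of the 22 could hardly change, so this count does not measure robustness. No called intervals overlapped, only 18 peaks had high backgrounds, and dense segments were defined by their number of peaks. The number of peaks fell from 9717 to 5404 at a −log10 q of 5, to 2473 at 10 and to 2147 at a fold of 5, and it stayed at 9717 or 9554 when peaks that overlap or lie within 500 bp were merged. The ratio of observed to random distance between summits ran from 0.54 to 0.76, and the density ratio of X from 0.11 to 0.19, each passing its permutation test in these settings, while weak peaks alone gave 0.16 on X (adjusted permutation p = 0.0629). The excess on chromosome 13 (3.72) was 1.69 at a −log10 q of 5 and no longer passed at 10 (1.13), at a fold of 5 (1.17) or without the dense segments (1.21), where 11 of its 18 bins were left. The fewer peaks or bins counted are part of each such setting, and the cause was not tested further. With 10 or 20 summits per bin, or a fold of 5 to mark strong peaks, the ratio inside dense segments ran from 1.64 to 2.05 for strong peaks and from 10.5 to 16.3 for weak ones. The repeat and centromere filter, the start site windows, the motif, 6-mer and strength settings and the gene windows were not run, for lack of the sequence and annotation of hg19. Depth limits the list to folds of about 3.01 or more at average coverage, and with 1 library no value has an error between cultures.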

Other observations

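No test was run for the values in this part, and the listing of gaps was chosen after the peaks were seen. Long stretches without a called summit were most frequent on chromosome X, which held 4 of the 12 widest gaps between neighbouring summits. Wide gaps come with the low number of peaks on X, and the number expected from it was not computed. The widest ran from 77378795 to 102786197, over 25.4 Mb. The others on X spanned 13.5, 11.1 and 10.1 Mb. On the autosomes the widest gaps were 21.7 Mb on chromosome 1 from 120905886 to 142571577, 19.6 Mb on chromosome 9 from 46897405 to 66503359 and 13.6 Mb on chromosome 16 from 32830954 to 46391408. The gap on chromosome 13 (9.59 Mb) ended shortly before the first of its dense segments. Assembly gaps were not marked here, so how much of each stretch can be aligned to is not known.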
